A study of Homo sapiens with 6 samples.

How the data were processed

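Gene expression was measured in NCI-H727 cells, an established human cell line grown from a lung carcinoid, a neuroendocrine tumour of the lung. Cells received a negative control siRNA (si-NC) or an siRNA against PROX1 (si-PROX1), each at 20 nmol/L, and were kept for 72 h, per the labels' protocols. The medium held 10% serum, and 250 ng of total RNA per sample was labelled with biotin for a whole-transcript array, per the labels. Each group had 3 samples, with 1 array per sample and 6 arrays in all.

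The deposited values are log2 signals, 1 per probe set and array, and no scanner files were used here. RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set, and the Transcriptome Analysis Console are named in the submitters' processing notes. Their versions, the RMA variant and the genome build are not given in the sources used here. Array medians lay between 4.07 and 4.13 on the log2 scale and array maxima between 19.7 and 19.9. A between-array normalization of this kind sets the arrays to a shared distribution, so a change of total RNA per cell would not be visible. Signals near the bottom of the scale are compressed towards background, which shrinks fold changes of dim genes.

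The table held 135750 probe sets. GEO's platform annotation listed 1 gene symbol for 36176 of them, several for 1119 and none for 98455. Symbols were checked against the gene table of human assembly GRCh38.p14, by Entrez identifier for 25516 probe sets and by name for 9899, and 761 kept the listed name. This changed 0 symbols. No coordinates are given because the build behind the probe sets is not stated. A gene was represented by its probe set with the highest mean over all 6 arrays, and probe sets with several symbols named no gene. Genes whose mean lay below the median of all row means (4.075 on the log2 scale) were left out, and 23088 of the 33616 symbols were tested. Not every gene chosen for reporting whatever its result was analysed here.

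The design holds a single comparison, si-PROX1 against si-NC. It was fitted with limma 3.58.1 in R 4.3.3 (tables read with the package data.table, version 1.17.8), using lmFit and eBayes with an intensity trend on the deposited log2 values and no covariate. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the 23088 genes, with a threshold of 0.05. Every adjusted p of a gene is from this limma fit unless another setting is named, and every SE is limma's moderated standard error. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1. No source says whether the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

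Before the data were examined, 32 gene lists were written from general knowledge of PROX1, neuroendocrine lung tumours, transfection responses and cell types, with 914 different genes. They cover neuroendocrine secretory genes, neuroendocrine and lung lineage transcription factors, neuronal genes, the Notch pathway, lymphatic endothelial genes, cell cycle G1/S, cell cycle G2/M, CDK inhibitors and D cyclins, p53 targets, apoptosis regulators, interferon response, antigen presentation, NF-kB and inflammatory genes, epithelial junction and keratin genes, mesenchymal genes and matrix metalloproteinases. They also cover integrins and focal adhesion, TGF-beta and BMP response, Wnt targets, YAP/TEAD targets, receptor tyrosine kinase and MAPK feedback, cholesterol, fatty acids, hepatic and HNF4A targets, glycolysis and hypoxia, ATF4 and amino acid response, endoplasmic reticulum chaperones, NRF2 targets, metallothioneins and oxidative phosphorylation. Markers of other lung epithelial cell types and of blood and stromal cells complete them. Each list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 32 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in a shared direction and does not compare the list with other genes.

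The genes named in the text follow a rule that was also fixed before the data were examined. It takes PROX1, a set of genes reported whatever their result, and the 14 largest rises and the 14 largest falls past the threshold whose 3 si-PROX1 arrays all lie on the same side of the 3 si-NC arrays. Symbols of unnamed loci, small and antisense RNAs, olfactory receptors and open reading frames are excluded from the largest changes. Of each list described it takes up to 4 members with the lowest adjusted p, and any member past the threshold with a log2 fold change of at least 1 in size. For the remaining lists at the end of the Results, only the latter are named. Members that went against the direction of a called list, and a pair of histone genes, were named after their values were seen, and the text says so.

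The fits were tested on simulated data with the 23088 genes and a 3 against 3 design. The fit recovered 5.97% of 67 genes changed by 0.5 on the log2 scale, 53.7% of 67 changed by 1 and 93.9% of 66 changed by 2. Of its 107 calls, 5 were false. The simulation changed far fewer genes than the 4035 that passed in the real comparison, and its noise was independent between genes. Its shares are therefore a check of the code and do not give the recovery in the real data. The alternatives were a further quantile normalization, centring each array on its median, no filter on dim genes, a stricter filter at the 75th percentile, the mean of all probe sets of a gene, eBayes without a trend, array weights, the replicate number as a block, leaving out each array, and an adjusted p under 0.01. Restricting the fit to protein-coding genes was added after the data had been seen.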

Results

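The data are log2 expression values from 6 whole-transcript arrays of NCI-H727 lung carcinoid cells, 3 transfected with a control siRNA (si-NC) and 3 with an siRNA against PROX1 (si-PROX1) for 72 h. The comparison asks which genes differ in expression when PROX1, a homeobox transcription factor, is knocked down. Over the 23088 genes tested, Pearson's r between arrays was 0.994 to 0.996 within si-NC, 0.993 to 0.995 within si-PROX1 and 0.984 to 0.990 between the groups. These correlations are across genes, which are not independent replicates. The first principal component held 51.8% of the variance and separated the groups, and the second held 18.1%.

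PROX1 itself was read first. Its level was 11.50 ± 0.26 on the log2 scale in si-NC (SD, n = 3) and 9.18 ± 0.29 in si-PROX1 (SD, n = 3). The log2 fold change was -2.32 with a standard error of 0.18 (limma, adjusted p = 1.11e-06), which is 20.0% of the control level or 5.01-fold lower. The labels name 1 siRNA against PROX1 and do not say whether it is a single sequence or a pool, so the comparison holds the effects of that siRNA whatever their route. The 3 si-PROX1 arrays all lay below the 3 si-NC arrays, and the exact two-sided permutation test gave p = 0.1, the smallest this design allows. PROX1 is represented by 1 probe set, TC0100011566.hg.1, and its fall ranked 6 among the genes tested.

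**Figure D1:**
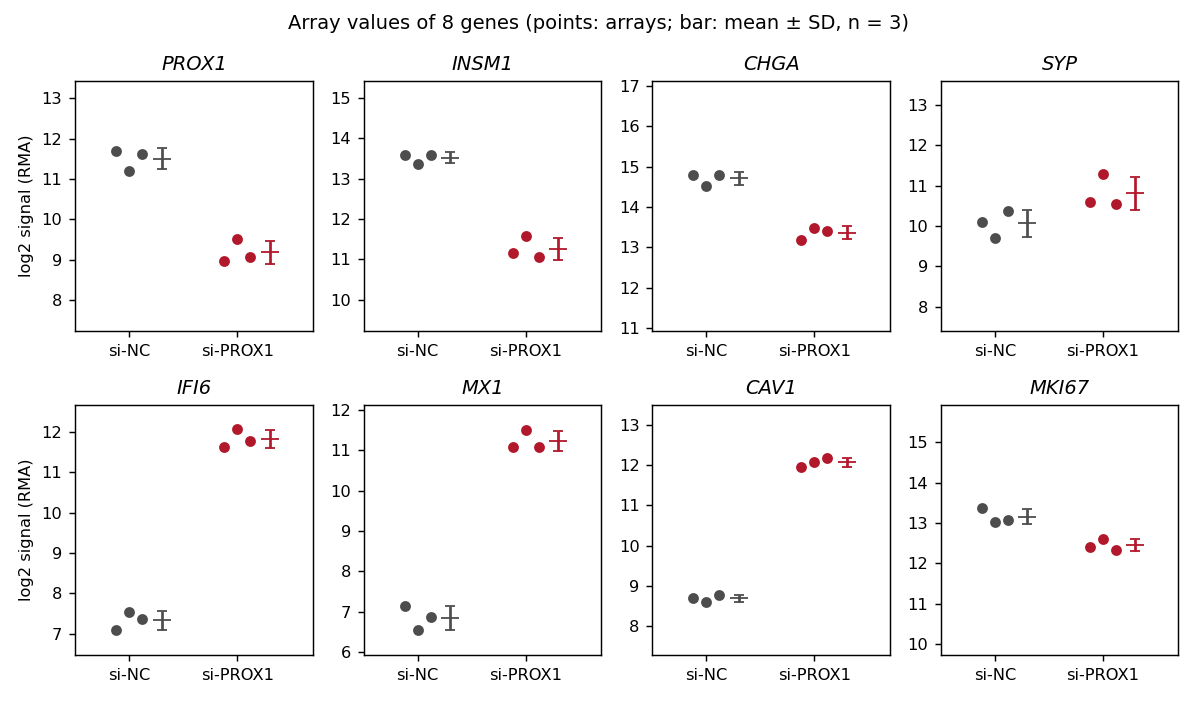
Log2 array signal (vertical axis, 8 panels of equal height) in the si-NC and si-PROX1 groups for PROX1, INSM1, CHGA, SYP, IFI6, MX1, CAV1 and MKI67. Points are single arrays and bars are the mean ± SD (n = 3); PROX1 falls from a mean of 11.50 to 9.18 and IFI6 rises from 7.34 to 11.82.

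Expression changed widely after si-PROX1. By limma with Benjamini-Hochberg adjustment, 1976 genes were higher and 2059 were lower, together 17.5% of the genes tested. Changes of at least 2-fold were more often rises, with 443 genes higher and 238 lower. Among the 14265 protein-coding genes 1799 were higher and 1441 lower. Among the 5311 pseudogenes 58 were higher and 484 lower, and among the 1434 long non-coding RNA genes 63 were higher and 37 lower. For 2431 pseudogenes the parent gene that their symbol names was also tested. Their mean log2 fold change was -0.46 for 766 whose parent fell, 0.09 for 263 whose parent rose and -0.17 for 1402 whose parent did not pass, of which 94 fell and 5 rose. The 3 + 3 arrays did not overlap for 3975 of the 4035 changed genes, and for 32.2% of all genes tested, where chance gives 10%. The number of lower genes varied with the array left out. It was 1222 without si-NC replicate 3, 1334 without si-NC replicate 1, 1454 without si-PROX1 replicate 3 and 1983 without si-NC replicate 2. The number of higher genes was also smaller with each array left out, at 1480 to 1817. The number of lower pseudogenes was 267 without si-NC replicate 3. The number of all lower genes was 1355 when eBayes was run without an intensity trend.

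The largest rises were led by antiviral genes that interferon induces. IFI6 was 22.4-fold higher (log2 fold change 4.49, SE 0.17, adjusted p = 3.66e-09) and MX1 20.8-fold (log2 fold change 4.38, SE 0.19, adjusted p = 6.28e-09). IFIT1 rose from 4.05 ± 0.28 in si-NC (SD, n = 3) to 7.93 ± 0.14 in si-PROX1 (SD, n = 3) on the log2 scale (limma, adjusted p = 3.38e-08). Its si-NC mean lies under the dim filter's bound of 4.075 and is not clearly above background, so the difference is a lower bound and its place among the largest rises is uncertain. CAV1, the main coat protein of caveolae, was 10.4-fold higher (log2 fold change 3.37, SE 0.14, adjusted p = 4.07e-09). RSPO3, a secreted enhancer of Wnt signalling, rose 9.31-fold from a dim si-NC mean of 4.98. IRF9, the DNA-binding subunit of the interferon-activated factor ISGF3, rose 8.89-fold. The secreted cysteine protease inhibitors CST1 and CST4 rose 9.14-fold and 7.37-fold, from dim si-NC means of 4.91 ± 0.82 and 5.56 ± 0.26 (SD, n = 3). The sequences of these paralogs are alike, so their signals may not be independent. The membrane ubiquitin ligase MARCHF4 rose 7.58-fold, the glucose transporter SLC2A3 7.34-fold and the cytochrome P450 enzyme CYP2S1 7.13-fold. PCYT1B, an enzyme of phosphatidylcholine synthesis, rose 6.94-fold, the protein C receptor gene PROCR 6.81-fold and the carbonic anhydrase gene CA12 6.37-fold. Adjusted p was at most 2.35e-05 for these 14 genes.

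The largest falls were led by NSG2, GP2 and PADI2. NSG2, a neuronal vesicle protein, was 7.62-fold lower (log2 fold change -2.93, SE 0.12, adjusted p = 4.07e-09). GP2, a secretory granule membrane protein, was 7.19-fold lower (log2 fold change -2.85, SE 0.11, adjusted p = 3.66e-09), and the arginine deiminase gene PADI2 was 6.50-fold lower (log2 fold change -2.70, SE 0.16, adjusted p = 1.19e-07). INSM1, a transcription factor used as a neuroendocrine marker, was 4.78-fold lower (log2 fold change -2.26, SE 0.14, adjusted p = 1.49e-07). The cancer-testis antigen genes GAGE10 and GAGE2A were 5.59-fold and 5.32-fold lower; these copies share most of their sequence, so the array cannot be taken to separate them. The cardiolipin acyltransferase gene LCLAT1 was 4.59-fold lower, the vesicular monoamine transporter gene SLC18A1 4.51-fold, and PTF1A, a transcription factor of pancreatic and neural development, 4.37-fold. ADCYAP1, which encodes a neuropeptide, was 4.31-fold lower and KITLG, the ligand of the receptor KIT, 4.19-fold. The creatine transporter gene SLC6A8 was 3.78-fold lower, PIK3R5, a regulatory subunit of phosphoinositide 3-kinase, 3.74-fold, and the calcium-binding protein gene CALB1 3.73-fold. Adjusted p was at most 0.000202 for these 14 genes.

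Of the 32 gene lists, 17 passed the camera test at the preset correlation, 13 towards higher and 4 towards lower expression. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.157, and 6 had an unadjusted p under 0.05. Fry called 13 lists, all of them among the 17 and in the same direction. For the lists, counts of members are over all genes tested unless they are said to be adjusted over the list alone.

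Transcription factors of the neuroendocrine and lung lineages fell as a list. Of 21 tested members 5 fell, 0 rose and 16 did not pass, with the same counts adjusted over the list alone. The camera test gave adjusted p = 0.00485, and adjusted p = 0.285 with an estimated correlation. Beside INSM1, ST18 was 2.30-fold lower (log2 fold change -1.20, SE 0.22, adjusted p = 0.00148) and ISL1 2.05-fold lower (log2 fold change -1.04, SE 0.18, adjusted p = 0.00124). RFX6, a regulator of endocrine differentiation, was 1.81-fold lower (log2 fold change -0.85, SE 0.15, adjusted p = 0.00115). A further probe set of ISL1 had a log2 fold change of -0.33 and did not pass. NKX2-1, a lung lineage factor, lay near the bottom of the scale at 4.38 ± 0.25 in si-NC and 3.89 ± 0.19 in si-PROX1 (SD, n = 3), and did not pass (limma, adjusted p = 0.130).

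Neuroendocrine secretory genes moved in both directions. Of 40 tested members 12 rose, 8 fell and 20 did not pass, with the same counts adjusted over the list alone, and the list did not pass the camera test (adjusted p = 0.164, and adjusted p = 0.735 with an estimated correlation). CHGA, which encodes the granule protein chromogranin A, was 2.55-fold lower (log2 fold change -1.35, SE 0.11, adjusted p = 2.09e-06). CALCA, the calcitonin gene, was 2.67-fold lower (log2 fold change -1.42, SE 0.08, adjusted p = 8.80e-08), and SLC18A1 fell as given above. STX1A, a membrane fusion protein of exocytosis, rose 2.68-fold, the granule protein gene PTPRN 2.11-fold, the neuronal transmembrane gene DNER 3.50-fold and the ubiquitin hydrolase gene UCHL1 1.44-fold, with adjusted p of at most 0.000902. SYP, which encodes the vesicle protein synaptophysin, was 1.67-fold higher (log2 fold change 0.74, SE 0.21, adjusted p = 0.0230). The SYP call was lost without si-NC replicate 1 (adjusted p = 0.0567), si-NC replicate 2 (adjusted p = 0.0966) or si-PROX1 replicate 2 (adjusted p = 0.0843), and with eBayes without trend (adjusted p = 0.0821).

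Neuronal genes were higher as a list. Of 26 tested members 9 rose, 2 fell and 15 did not pass; adjusted over the list alone 11 rose and 2 fell. The camera test gave adjusted p = 0.0368, and adjusted p = 0.427 with an estimated correlation. CRMP1, a protein of axon guidance, rose 2.40-fold, the neuronal gene RUNDC3A 1.97-fold and the splicing regulator RBFOX2 1.76-fold, while the neurofilament gene NEFM fell 1.72-fold. NEFL, another neurofilament gene named after its value was seen, fell 1.51-fold (adjusted p = 0.00995), a call lost without si-NC replicate 1 (adjusted p = 0.0591). A further probe set of CRMP1 had a log2 fold change of 0.22 and did not pass. The list's call was lost without si-PROX1 replicate 1 (adjusted p = 0.0690), in protein-coding genes alone (adjusted p = 0.177) and by fry (adjusted p = 0.0822).

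Genes of the Notch pathway, which restrains neuroendocrine differentiation in several tissues, went both ways. Of 27 tested members 3 rose, 5 fell and 19 did not pass; adjusted over the list alone 3 rose and 6 fell. The list did not pass (camera adjusted p = 0.413, and adjusted p = 0.735 with an estimated correlation). The receptors NOTCH3 and NOTCH2 rose 2.39-fold and 2.30-fold, NOTCH3 from a dim si-NC mean of 4.90, and the target gene HEY1 rose 1.82-fold. The target gene HEY2 fell 3.22-fold, and the ligand gene DLL3 fell from 4.66 to 3.52 on the log2 scale, the latter under the dim filter's bound, with adjusted p of at most 0.00185 for these 5 genes. NOTCH1 (log2 fold change -0.09, SE 0.21, adjusted p = 0.857) and HES1 (log2 fold change -0.28, SE 0.11, adjusted p = 0.109) did not pass.

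Interferon response genes showed the strongest shift of the 32 lists. Of 34 tested members 25 rose, 0 fell and 9 did not pass; adjusted over the list alone 27 rose and 1 fell. The median log2 fold change was 1.03, and the camera test gave adjusted p = 4.28e-23, and adjusted p = 0.157 with an estimated correlation. Beside IFI6, MX1, IFIT1 and IRF9, PARP9 rose 4.24-fold, OAS1 3.94-fold, SAMD9 3.86-fold and RIGI 3.71-fold. OAS1 makes a second messenger that activates RNA degradation, and RIGI is a sensor of double-stranded RNA. IFITM3 rose 2.85-fold, IFI27 2.82-fold from a dim si-NC mean of 4.48, DTX3L 2.80-fold, PARP14 2.73-fold and OAS3 2.58-fold. IFITM2 rose 2.13-fold, the RNA sensor gene IFIH1 2.05-fold, and SAMD9L and DDX60 2.04-fold each; IFITM2 and IFITM3 are close paralogs. IFI44L, with a si-NC mean of 3.62 that is also under the dim filter's bound, was higher in si-PROX1 at 4.72, a difference that is likewise a lower bound (adjusted p = 0.0192), and its call was lost without si-NC replicate 2 (adjusted p = 0.0972), si-PROX1 replicate 2 (adjusted p = 0.0676) or si-PROX1 replicate 3 (adjusted p = 0.0504), and with eBayes without trend (adjusted p = 0.0607). Adjusted p was at most 0.00195 for the other members named.

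Antigen presentation genes and inflammatory genes were also higher as lists. Of 19 antigen presentation genes tested 8 rose, 2 fell and 9 did not pass; adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.00485, and adjusted p = 0.285 with an estimated correlation). The immunoproteasome subunit gene PSMB9 rose 2.84-fold, the peptide-trimming enzyme ERAP2 2.25-fold and the peptide-loading factor TAPBP 2.06-fold. HLA-F and HLA-C, paralogs that share sequence, rose 1.80-fold and 1.75-fold. The members that fell, named after their values were seen, were the general chaperones PDIA3 (1.30-fold, adjusted p = 0.00353) and CANX (1.16-fold, adjusted p = 0.0260). The PDIA3 call was lost with eBayes without trend (adjusted p = 0.112) and the CANX call there (0.337), with the replicate block (0.0541), and without si-NC replicate 2 (0.107), si-NC replicate 3 (0.121) or si-PROX1 replicate 2 (0.0833). Of 25 NF-kB and inflammatory genes 9 rose, 0 fell and 16 did not pass; adjusted over the list alone 10 rose and 0 fell (camera adjusted p = 5.71e-05, and adjusted p = 0.157 with an estimated correlation). Complement C3 rose 3.55-fold from a dim si-NC mean of 4.15, TNFAIP8 3.28-fold, the NF-kB inhibitors TNFAIP3 and NFKBIA 2.16-fold and 1.85-fold, and the cytokine gene LIF 2.11-fold. Adjusted p was at most 0.00644 for the genes named here that rose.

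Blood and stromal cell markers, fixed as markers of other cell types, did not pass as a list, with 3 members higher, 1 lower and 12 not past of 16; adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.276, and adjusted p = 0.450 with an estimated correlation). Beside the interferon, antigen presentation and inflammatory genes, the macrophage-associated genes CD68, CD14 and LYZ were 1.88-fold, 2.02-fold and 1.44-fold higher in si-PROX1, with adjusted p of at most 0.00679. HBA1, a globin gene, was 1.63-fold lower (adjusted p = 0.0246), a call lost without si-NC replicate 1 (adjusted p = 0.0953), si-NC replicate 2 (0.0593), si-NC replicate 3 (0.0534) or si-PROX1 replicate 3 (0.117). Of 16 markers of other lung epithelial cell types 1 rose, 0 fell and 15 did not pass; adjusted over the list alone 0 rose and 0 fell (camera adjusted p = 0.673, and adjusted p = 0.735 with an estimated correlation). The riser was ABCA3, a lipid transporter of alveolar type II cells (log2 fold change 0.67, SE 0.22, adjusted p = 0.0476). The ABCA3 call was lost when any array but si-NC replicate 1 was left out, with adjusted p of 0.174 without si-NC replicate 2, 0.0705 without si-NC replicate 3, 0.0946 without si-PROX1 replicate 1, 0.0909 without si-PROX1 replicate 2 and 0.0880 without si-PROX1 replicate 3. Without si-NC replicate 2 its log2 fold change was 0.43. The call was also lost with each array centred on its median (adjusted p = 0.0620), no dim filter (0.0764), eBayes without trend (0.0726), array weights (0.0656) and the replicate block (0.0618).

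Both cell cycle lists passed the camera test towards lower expression at the preset correlation. Of 40 G2/M genes tested 28 fell, 0 rose and 12 did not pass; adjusted over the list alone 32 fell and 1 rose (camera adjusted p = 2.76e-14, and adjusted p = 0.157 with an estimated correlation). Of 38 G1/S genes 20 fell, 1 rose and 17 did not pass; adjusted over the list alone 24 fell and 1 rose (camera adjusted p = 1.71e-10, and adjusted p = 0.285 with an estimated correlation). The median log2 fold change was -0.48 in both lists. MKI67, the proliferation marker Ki-67, was 1.63-fold lower (log2 fold change -0.71, SE 0.12, adjusted p = 0.00107). The mitotic genes KIF2C, CCNA2, AURKA and PLK1 were 1.94-fold, 1.66-fold, 1.57-fold and 1.44-fold lower. A further probe set of KIF2C had a log2 fold change of -0.42 and did not pass. The replication and repair genes EXO1, CLSPN, MCM4 and MCM7 were 1.94-fold, 1.92-fold, 1.65-fold and 1.45-fold lower, with adjusted p of at most 0.000289 for these 8 genes. The member that rose was the thymidine kinase gene TK1 (log2 fold change 0.68, SE 0.14, adjusted p = 0.00414), named after its value was seen. CDK inhibitors and D cyclins did not pass as a list, with 1 member higher, 2 lower and 11 not past of 14; adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.900, and adjusted p = 0.951 with an estimated correlation). The riser was the CDK inhibitor gene CDKN1A, 1.90-fold higher (log2 fold change 0.92, SE 0.14, adjusted p = 0.000357). The members that fell were RBL1, a retinoblastoma-like gene, 1.71-fold lower (adjusted p = 0.00299), and the kinase gene CDK6, 1.76-fold lower (adjusted p = 0.0169). The CDK6 call was lost without si-NC replicate 1 (0.0751), si-NC replicate 3 (0.0694) or si-PROX1 replicate 3 (0.0832). The CDK inhibitor gene CDKN1B did not pass (log2 fold change -0.43, SE 0.14, adjusted p = 0.0551) but was lower past the threshold with the stricter dim filter (0.0434), array weights (0.0430) and protein-coding genes only (0.0465), with a range of 0.0430 to 0.167 over all settings.

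The lists of integrin and focal adhesion genes and of YAP/TEAD targets passed the camera test towards higher expression at the preset correlation. Of 23 integrin and focal adhesion genes tested 13 rose, 1 fell and 9 did not pass; adjusted over the list alone 16 rose and 1 fell (camera adjusted p = 6.58e-11, and adjusted p = 0.157 with an estimated correlation). Beside CAV1, the integrin genes ITGA2, ITGA5, ITGA3 and ITGB6 rose 4.88-fold, 3.20-fold, 2.94-fold and 2.54-fold, with adjusted p of at most 5.19e-05. CAV2, the member that fell, was 1.51-fold lower (adjusted p = 0.0173) and was named after its value was seen; its call was lost without si-NC replicate 1 (0.0818) or si-PROX1 replicate 2 (0.0561). Both further probe sets of ITGB6 did not pass, with log2 fold changes of 0.13 and 0.12, and the mean of its probe sets did not pass either (log2 fold change 0.53, adjusted p = 0.0974). Of 18 YAP/TEAD target genes 10 rose, 2 fell and 6 did not pass; adjusted over the list alone 11 rose and 3 fell (camera adjusted p = 3.16e-07, and adjusted p = 0.157 with an estimated correlation). MYOF, a membrane repair protein, rose 4.83-fold, the matricellular genes CCN2 and CCN1 3.09-fold and 2.27-fold, CRIM1 2.41-fold, PTPN14 2.22-fold and IGFBP3 2.13-fold, with adjusted p of at most 0.00195. GADD45A, a DNA damage response gene, and FJX1 fell 1.60-fold and 1.61-fold (adjusted p = 0.00299 and 0.0188) and were named after their values were seen. The FJX1 call was lost without si-NC replicate 1 (0.0546), si-NC replicate 3 (0.117) or si-PROX1 replicate 1 (0.0505).

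Epithelial junction and keratin genes were higher as a list, whereas mesenchymal genes were mixed. Of 35 epithelial genes tested 11 rose, 1 fell and 23 did not pass; adjusted over the list alone 12 rose and 2 fell (camera adjusted p = 3.88e-06, and adjusted p = 0.385 with an estimated correlation). The serine protease gene PRSS8 rose 4.78-fold, the protease inhibitor genes SPINT1 and SPINT2 2.11-fold and 1.81-fold, the desmosome gene DSP 2.09-fold and the keratin gene KRT19 1.48-fold, with adjusted p of at most 0.000239. The keratin gene KRT18, named after its value was seen, fell 1.20-fold (adjusted p = 0.0109), a call lost with eBayes without trend (adjusted p = 0.228). CDH1, which encodes E-cadherin, did not pass (log2 fold change 0.32, SE 0.13, adjusted p = 0.118) but did without si-PROX1 replicate 3 (log2 fold change 0.44, adjusted p = 0.0363). Of 27 mesenchymal genes 2 rose, 4 fell and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.701, and adjusted p = 0.883 with an estimated correlation). Fibronectin FN1 rose 2.98-fold and N-cadherin CDH2 1.90-fold, while thrombospondin THBS1 fell 2.40-fold, with adjusted p of at most 0.00531. SNAI2 fell 1.53-fold (adjusted p = 0.0187), and its call was lost without si-NC replicate 1 (adjusted p = 0.0628), si-NC replicate 3 (0.0593), si-PROX1 replicate 1 (0.0548) or si-PROX1 replicate 3 (0.0817). VIM, which encodes vimentin, did not pass (log2 fold change -0.22, SE 0.22, adjusted p = 0.580). Of 18 matrix metalloproteinases and inhibitors 3 rose, 3 fell and 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.247, and adjusted p = 0.720 with an estimated correlation). The protease genes MMP9, MMP24 and MMP13 rose 4.95-fold, 2.72-fold and 1.51-fold and ADAM9 fell 1.58-fold, with adjusted p of at most 0.00169.

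Glycolysis and hypoxia genes were higher as a list at the preset correlation. Of 29 tested members 21 rose, 0 fell and 8 did not pass; adjusted over the list alone 22 rose and 1 fell (camera adjusted p = 9.26e-18, and adjusted p = 0.157 with an estimated correlation). Beside SLC2A3 and CA12, the glycolytic enzyme genes ALDOC and PGAM1 rose 4.04-fold and 2.23-fold, the collagen prolyl hydroxylase gene P4HA1 2.27-fold and the mitophagy receptor gene BNIP3L 1.98-fold, with adjusted p of at most 8.23e-06.

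Both lists of lipid metabolism genes passed the camera test towards higher expression at the preset correlation. Of 21 cholesterol genes tested 10 rose, 1 fell and 10 did not pass; adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 3.16e-07, and adjusted p = 0.246 with an estimated correlation). The synthesis genes MSMO1, SC5D and IDI1 rose 1.89-fold, 1.74-fold and 1.69-fold, while TMEM97 fell 2.43-fold, with adjusted p of at most 5.83e-05. Of 25 fatty acid genes 9 rose, 2 fell and 14 did not pass; adjusted over the list alone 10 rose and 3 fell (camera adjusted p = 0.0232, and adjusted p = 0.720 with an estimated correlation). CPT1A, which admits fatty acids to mitochondria, rose 2.53-fold and the acyl-CoA synthetase gene ACSL5 2.41-fold. PDK4, an inhibitor of pyruvate oxidation, fell 2.15-fold and the coactivator gene PPARGC1A 1.98-fold, with adjusted p of at most 0.000537 for these 4 genes. The call of the fatty acid list was lost without si-NC replicate 2 (adjusted p = 0.0610) or si-PROX1 replicate 2 (adjusted p = 0.0810), with array weights (0.0535), in protein-coding genes alone (0.138) and by fry (0.227).

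Stress response lists differed in direction. Of 21 NRF2 target genes 9 rose, 0 fell and 12 did not pass; adjusted over the list alone 13 rose and 0 fell (camera adjusted p = 3.16e-07, and adjusted p = 0.285 with an estimated correlation). The transporter gene ABCC3 rose 2.50-fold, the reductase paralogs AKR1C1 and AKR1C2 1.81-fold and 1.49-fold, and ferritin light chain FTL 1.32-fold (adjusted p = 0.000656), a call lost with eBayes without trend (adjusted p = 0.0850). Of 11 metallothioneins, metal-binding proteins with nearly shared sequences, 5 rose, 0 fell and 6 did not pass; adjusted over the list alone 7 rose and 0 fell (camera adjusted p = 0.000302, and adjusted p = 0.285 with an estimated correlation). MT1F rose 1.88-fold, MT1G 1.68-fold, MT2A 1.65-fold and MT1X 1.59-fold. Of 27 ATF4 and amino acid response genes 8 rose, 1 fell and 18 did not pass; adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.00471, and adjusted p = 0.620 with an estimated correlation). This list did not pass by fry (adjusted p = 0.0507). The serine synthesis gene PSAT1 rose 2.97-fold, DDIT4 2.66-fold and STC2 2.10-fold, while the stress-induced transcription factor gene ATF3 fell 2.12-fold. Of 25 genes on the endoplasmic reticulum chaperone list 2 rose, 6 fell and 17 did not pass. Adjusted over the list alone 2 rose and 7 fell (camera adjusted p = 0.0371, and adjusted p = 0.720 with an estimated correlation). This list also holds genes that are not chaperones, such as ERN1, XBP1 and SEC24D. The stress sensor gene ERN1 fell 1.99-fold and its target XBP1 1.63-fold, with adjusted p of at most 0.000251. PDIA3 fell 1.30-fold and SYVN1 rose 1.34-fold, calls lost with eBayes without trend (adjusted p = 0.112 and 0.0710). SEC24D, a vesicle coat gene named after its value was seen, rose 1.26-fold (adjusted p = 0.0228). Its call was lost with eBayes without trend (0.126), with the replicate block (0.0824), and without si-NC replicate 1 (0.0907), si-NC replicate 3 (0.0608) or si-PROX1 replicate 1 (0.0900). The chaperone list's own call was lost without si-NC replicate 1 (adjusted p = 0.0678), si-NC replicate 3 (0.0891) or si-PROX1 replicate 1 (0.0690). It was also lost with the stricter filter (0.0705), the mean of all probe sets (0.0606), eBayes without trend (0.127) and fry (0.0874).

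**Figure D2:**
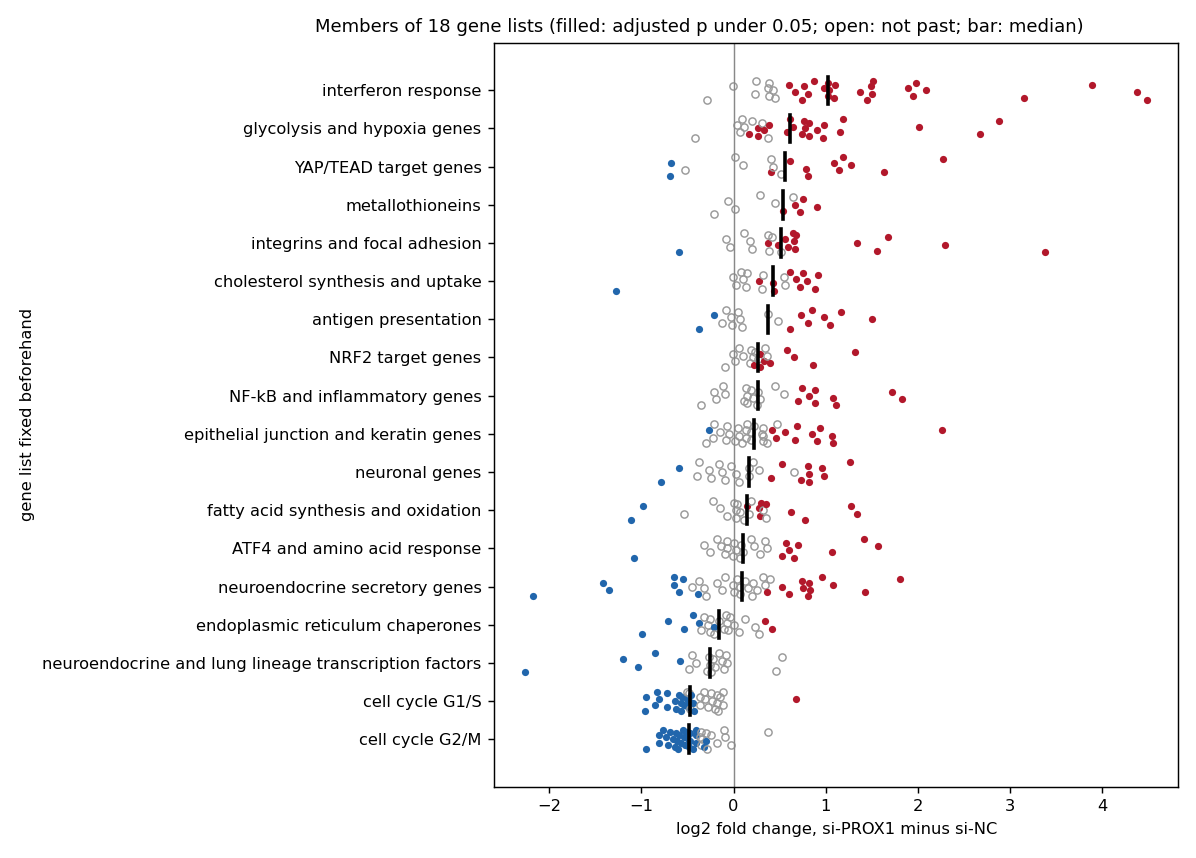
Log2 fold change, si-PROX1 minus si-NC (horizontal axis), of every tested member of the 17 gene lists that passed the camera test at the preset correlation and of the neuroendocrine secretory list (vertical axis). Filled points passed adjusted p under 0.05, open points did not, black bars are list medians, and height within a row only spreads the points; the interferon median lies at 1.03 and both cell cycle medians at -0.48.

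The remaining lists did not pass the camera test. TGF-beta and BMP response had 6 members higher, 4 lower and 22 not past of 32 (adjusted over the list alone 8 and 7; camera adjusted p = 0.192). Wnt targets had 3 higher, 2 lower and 11 not past of 16 (adjusted over the list alone 4 and 2; camera adjusted p = 0.277), and p53 targets had 4 higher, 4 lower and 14 not past of 22 (adjusted over the list alone 4 and 4; camera adjusted p = 0.701). Apoptosis regulators had 4 higher, 4 lower and 17 not past of 25 (adjusted over the list alone 5 and 4; camera adjusted p = 0.435). Receptor tyrosine kinase and MAPK feedback genes had 6 higher, 5 lower and 21 not past of 32 (adjusted over the list alone 6 and 6; camera adjusted p = 0.701). Hepatic and HNF4A targets had 5 higher, 6 lower and 11 not past of 22 (adjusted over the list alone 5 and 7; camera adjusted p = 0.394). Oxidative phosphorylation had 2 higher, 4 lower and 18 not past of 24 (adjusted over the list alone 3 and 9; camera adjusted p = 0.192). Lymphatic endothelial genes, among which PROX1 is a known regulator, had 0 higher, 1 lower and 5 not past of 6 (adjusted over the list alone 0 and 1; camera adjusted p = 0.673). The member that fell was the growth factor receptor gene KDR, 2.57-fold lower (log2 fold change -1.36, SE 0.17, adjusted p = 7.59e-05). Of the TGF-beta list PMEPA1 rose 2.56-fold, beside CCN2 and CCN1 given above. The p53 target TP53I3 rose 2.09-fold and PLK2 fell 2.13-fold. BCL2 of the apoptosis list fell 2.03-fold and DUSP5 of the MAPK feedback list 2.22-fold. Of the hepatic list FGB, APOA1 and FGA rose 2.70-fold, 2.09-fold and 2.04-fold. APOB, NR5A2 and NR0B2 fell 2.24-fold, 2.12-fold and 2.01-fold. Adjusted p was at most 0.00525 for these genes. Summary measures differed in sign for some lists that did not pass. The CDK inhibitor list had a median of -0.01 and a mean of -0.05 with a camera direction towards higher, and the receptor tyrosine kinase list a median of 0.01 and a mean of -0.02. The other lung epithelial list had a median of -0.03 and a mean of 0.04, and the blood and stromal list a median of -0.04 and a mean of 0.11, all 4 tested towards higher.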

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

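Outside the gene-level comparison, probe sets with no listed gene symbol or with several also changed between the groups, and were singled out because the comparison does not use them. Of 43215 such probe sets at or above the same filter, 128 were higher and 127 lower after si-PROX1 by limma with Benjamini-Hochberg adjustment over these probe sets, together 0.590%. Their log2 fold changes reached 2.94 and -2.86. Groups of 3 arrays are too small to test a single array as standing apart, and no technical batch is given in the labels.

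Among the tests in the paragraphs that follow, those on the siRNA duplex and on pseudogenes with an almost unmoved parent gene were chosen after the results were seen. The tests on intensity, on the pseudogenes' parent genes as a whole and on other splits were written down before their values were computed, though after the lists and largest changes had been seen.

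The 6 arrays can be split into 3 and 3 in 10 ways, the real split included, which is too few for a share under 0.05. Among these, a split with as many higher genes (1976), lower genes (2059), genes at least 2-fold higher (443) or at least 2-fold lower (238) was found 1 time in each case, the real split itself, and the highest other split gave 0 genes. For the gene lists the real split gave 17 calls, 1 split of 10 reached that number, and the highest other split gave 15. Every other split still holds unequal numbers of both groups on its sides, so part of the group difference remains in it. The group difference also adds to the spread within each side, which works against gene calls. The 0 genes of the other splits therefore do not show what chance alone would give. The cause of the 5 to 15 list calls in the other splits was not tested. An estimated correlation was used with the real split only, where it gave 0 calls.

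The interferon response list rose with a median log2 fold change of 1.03. An intensity-dependent bias of the deposited normalization is argued against: the median stood at percentile 100 of 10000 random lists matched on mean expression, whose 5th to 95th percentiles were -0.16 to 0.07. An effect particular to the si-PROX1 duplex rather than the loss of PROX1 stays open. Double-stranded RNA can induce these genes, and the labels name 1 siRNA against PROX1, without saying whether it is a pool. The si-NC cells also received an siRNA at 20 nmol/L for 72 h, so a response shared by both siRNAs would not appear as a difference. Of 11 tested type I and III interferon genes 0 were higher and 0 lower by limma, and at an unadjusted p under 0.05 0 were higher and 1, IFNA8, was lower (log2 fold change -0.56). All 11 had group means of at most 5.79, near the bottom of the scale, while 5 of 6 interferon receptor genes rose. Loss of PROX1 and an effect of the duplex cannot be told apart, because the labels name no other siRNA against PROX1 to compare.

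The cell cycle lists fell with a joint median of -0.48. The same matched comparison put this at percentile 0, against 5th to 95th percentiles of -0.13 to 0.05, which argues against an intensity-dependent bias of the deposited normalization. An effect particular to the si-PROX1 duplex rather than the loss of PROX1 stays open here too: the labels hold 1 siRNA against PROX1, and no value can separate the explanations. Slower division after loss of PROX1 is a hypothesis that these arrays do not test.

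Of 5311 pseudogene probe sets 484 were lower, 58 higher and 4769 not past the threshold, with a median of -0.14. The size of the median depended on the filter: it was -0.08 over 9273 pseudogenes with no dim filter and -0.21 over 2853 with the stricter filter. The median of the 5311 stood at percentile 0 of protein-coding lists matched on mean expression (5th to 95th percentiles -0.01 to 0.00). This argues against an intensity-dependent bias of the deposited normalization that protein-coding genes share. With 5311 members the matched medians vary little, so even a small shift reaches percentile 0. A bias particular to pseudogene probe sets is not covered by the comparison. Signal from the parent gene of the same sequence may account for part of the fall: among 2431 pseudogenes with a tested parent, the mean was 0.09 for 263 whose parent rose, -0.46 for 766 whose parent fell and -0.17 for 1402 whose parent did not pass. The first and second means differed by 0.55 (95% bootstrap interval 0.51 to 0.59, permutation p = 1e-05, the smallest these permutations can give). Pseudogenes were resampled singly, although those of a shared parent are not independent, so the interval is too narrow and the p too small. Whether parent signal accounts for the whole fall is not settled. Where the parent moved by under 0.1 and lay under 14 on the log2 scale, 158 pseudogenes changed by -0.0898 relative to the parent (95% bootstrap interval -0.127 to -0.0534). These parents were chosen by their measured change, so some that truly fell may be among them. The interval also treats pseudogenes of a shared parent as independent. Its bound was set after similar means had been seen and was passed narrowly, so no conclusion is drawn from it. A further 437 pseudogenes with an equally unmoved parent at 14 or more changed by -0.202 relative to it; they were set apart because signal near the top of the scale can be compressed, and no interval was computed for them. The count of lower pseudogenes fell to 267 without si-NC replicate 3, and whether anything else lowers them is open.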

How the results depend on the processing

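The restriction to protein-coding genes was chosen after the data were seen; all other settings were fixed before. PROX1 remained lower and past the threshold in every setting run, and with each array left out its log2 fold change lay between -2.49 and -2.22. With single arrays left out, 1480 to 1817 genes were higher, 1222 to 1983 lower, 373 to 518 at least 2-fold higher, 222 to 297 at least 2-fold lower, and 15 to 17 lists called. Without a trend in eBayes 1355 genes were lower, and at an adjusted p under 0.01, a stricter threshold by construction, 1231 were higher and 1102 lower; for the other settings the cause was not tested. The replicate block gave 1681 higher and 1594 lower genes. The arrays gave no sign that the replicate numbers pair the samples, though 3 arrays per group cannot settle this. Deviations of same-numbered arrays correlated at -0.19, -0.22 and -0.01, and 0 of the 3 si-NC arrays correlated best with its own number.

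With an estimated correlation 0 lists were called. The adjusted p was then 0.157 for interferon response, glycolysis and hypoxia, cell cycle G2/M, integrins, YAP/TEAD targets and NF-kB genes, 0.246 for cholesterol, and 0.285 for cell cycle G1/S, NRF2 targets, metallothioneins, antigen presentation and the lineage transcription factors. It was 0.385 for epithelial genes, 0.427 for neuronal genes, 0.620 for ATF4 genes and 0.720 for fatty acid and endoplasmic reticulum chaperone genes. By fry the adjusted p was 0.0822 for neuronal, 0.227 for fatty acid, 0.0507 for ATF4 and 0.0874 for chaperone genes. Chaperone genes also missed the threshold with the stricter dim filter (0.0705), the mean of all probe sets (0.0606) and eBayes without trend (0.127), fatty acid genes with array weights (0.0535) and protein-coding genes only (0.138), and neuronal genes with protein-coding genes only (0.177). With single arrays left out the adjusted p ranged from 0.0270 to 0.0690 for neuronal, 0.0144 to 0.0810 for fatty acid and 0.00829 to 0.0891 for chaperone genes; the cause was not tested.

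Reversals were seen only among results not past the threshold. The CDK inhibitor list turned with array weights (adjusted p = 0.944), protein-coding genes only (0.874), fry (0.976) and without replicate 2 of si-NC (0.858) or si-PROX1 (0.962), with a range of 0.726 to 0.962 over single arrays left out. The receptor tyrosine kinase list turned with array weights (0.953), protein-coding genes only (0.938) and without replicate 2 of si-NC (0.937) or si-PROX1 (0.962), with a range of 0.468 to 0.962, and the p53 list with protein-coding genes only (0.947). The log2 fold change of NOTCH1 was 0.000155 without si-NC replicate 1 and 0.0489 without si-PROX1 replicate 1, with a range of -0.27 to 0.0489. Of 192 genes taken by the naming rule or named later, besides PROX1, 180 passed the threshold; 20 of these lost it in some setting and 0 reversed, and 3 others passed it in some setting. Genes near the bottom of the log2 scale, where signal is little above background, are the least precise.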

Other observations

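The gene families in this part were chosen after the data had been seen, and their tests with them. Replication-dependent and other histone genes were lower as a family: of 63 tested 32 fell and 0 rose, with a median log2 fold change of -0.45 (camera adjusted p = 1.53e-14, and adjusted p = 0.151 with an estimated correlation). H2BC14 had a log2 fold change of -1.43 (limma adjusted p = 3.22e-05) and H2BC26 -1.10 (adjusted p = 0.00130), the largest falls among them. The direction of the median held in all 16 settings, from -0.50 to -0.39, but the number that fell was 18 with eBayes without trend. Histone genes share much of their sequence, so single members are uncertain.

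All 5 tested GAGE genes, cancer-testis antigens normally silent outside the germline, fell in all 16 settings, with a median of -1.90 (camera adjusted p = 7.38e-10, and adjusted p = 0.137 with an estimated correlation). Their copies are nearly alike, so the 5 values are not independent. Cytosolic ribosomal protein genes were slightly lower as a family, 11 of 56 falling and 0 rising with a median of -0.13 (camera adjusted p = 8.01e-05, and adjusted p = 0.226 with an estimated correlation), and 2 falling with eBayes without trend. The family was taken by symbol and so includes paralogs named as ribosomal-protein-like. Of these, RPL7L1 and RPL22L1 had the largest falls of the family (log2 fold change -0.75 and -0.59), while RPL3L, RPL26L1, RPL39L and RPS27L did not pass. Zinc finger genes were lower in 44 and higher in 10 of 421, with a median of -0.11 (camera adjusted p = 0.0243, and adjusted p = 0.559 with an estimated correlation), and 16 were lower without si-NC replicate 3. Over the 16 settings their median ranged from -0.16 to -0.07. Of all 14265 protein-coding genes tested 1441 were lower and 1799 higher. Zinc finger genes thus stood out by few rises, while their share of falls was close to that of all protein-coding genes. Small nucleolar RNA genes were lower in 15 and higher in 1 of 163, with a median of -0.17 (camera adjusted p = 0.0105, and adjusted p = 0.229 with an estimated correlation), and 7 were lower without si-NC replicate 3. Over 15 settings their median ranged from -0.21 to -0.08, the latter over 220 genes with no dim filter. SNORD3A, SNORD3B-2, SNORD3C and SNORD3D had the lowest adjusted p of the family, with log2 fold changes of -0.73, -0.76, -0.86 and -0.85. They are copies of the same small nucleolar RNA, so their values are not independent.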
